A study of Mus musculus with 10 samples.

How the data were processed

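Total RNA of the spinal cord at thoracic segment T10 was measured in ICR mice, an outbred laboratory stock, after a sham operation and at 1 day, 3 days, 1 week and 3 weeks after spinal cord injury. Per the labels, all animals were 4 weeks old, those of the group at 3 weeks after injury included. If this is the age at surgery, the animals of later groups were older at collection. Age and time after injury could then not be told apart, and the labels give sham no time after surgery. The design text describes 15 mice in 5 groups of 3, with the RNA of a group mixed by equal mass before hybridisation, so each group is 1 pool. Per the labels' protocols, tissue was snap frozen, RNA was extracted with Trizol and purified on columns with a DNase step, and Affymetrix whole-transcript kits made the biotin-labelled single-stranded DNA. Each pool is present as a gene-level sample and as an exon-level sample, which makes 10 samples, and samples were grouped by the time and level in their titles.

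The deposited gene-level table holds 1 log2 signal per transcript cluster, a set of probes that covers 1 gene locus, for 23332 clusters. The deposited exon-level table holds 1 log2 signal per probe set, a few probes within 1 exon, for 229581 probe sets. Neither table names the base of the logarithm. The highest value would be an intensity of 9097 with base 2 and of 514577 with the natural logarithm, which is above the 65535 that a 16-bit scanner can record, so base 2 was used. Per the submitters' processing notes, the GCOS software and the mm8 mouse genome build were used. The background correction, normalization and probe summary are not given in the sources used here. Array medians spanned 0.24 in the gene-level table and 0.43 in the exon-level table, on the log2 scale, so the 5 arrays did not share 1 distribution. An unequal scaling of the arrays would add about the same amount to every difference between a pair of arrays.

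Gene names came from the platform annotation. Of the clusters, 14996 had 1 gene symbol, 1019 had several and 7317 had none. Of the probe sets, 209279 had 1 symbol, 4446 had several and 15856 had none. Symbols were brought up to date through the gene identifiers of a RefSeq table of the GRCm38.p6 assembly, which held 14941 of the single-gene clusters, and at the exon level through symbols and synonyms, which gave a current name to 16335 of 16380 symbols. No coordinates were used, because that assembly differs from the submitters' build. Clusters and probe sets with no symbol or several were not named.

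A cluster was kept if its highest value on the 5 arrays was at or above 3.79, the 40th percentile of all gene-level values. Where several clusters carried 1 symbol, the one with the highest mean stood for the gene. This left 11280 genes. Values were used as deposited, and differences are log2 values of the later array minus those of sham or of the preceding time. With 1 array per group there is no replicate, so no test, p-value or standard error was computed. The design text selects genes by a false discovery rate of 0.05 and a fold of 2, and here the 2-fold rule of size alone was applied. A gene was called higher or lower if it differed by at least 2-fold, which is 1 on the log2 scale.

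For each gene, probe sets at or above the 40th percentile of exon-level values (4.85) on at least 1 array gave the median and SD of their log2 differences. At least 1 such probe set was found for 14378 genes, 11055 of which were also measured at the gene level. This SD describes probe sets within 1 pair of arrays and not animals. Both levels have the same 5 group labels and were taken as coming from the same pools. Whether they are summaries of the same hybridisations is not given in the sources used here, and they were never averaged or used as replicates. The number of arrays limits the precision of every value, and the tables carry no detection call.

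Before the data were examined, 40 gene lists were fixed: 19 of cell type markers, 20 of pathways and 1 of known long noncoding RNAs. Markers of skeletal muscle, erythrocytes, Schwann cells and meninges were included because dissection or injury can bring such tissue in. For each list, the median log2 difference of its measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these arrays and is not a p-value. A 95% interval came from 2000 bootstrap draws over members. A list was said to lie beyond random lists above the 97.5th or below the 2.5th percentile.

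The rule for named genes was also fixed before the data were examined. Against sham it takes the 6 largest rises and the 6 largest falls among genes with at least 4 probe sets of which at least 75% moved the same way, and for each step between times the 4 largest. From each list it takes up to 2 members with the largest rise and 2 with the largest fall. Of the long noncoding RNAs it takes the 5 largest rises and falls at any time, and each known one past 2-fold. A long noncoding RNA is a gene with that type in the RefSeq table.

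The calculations were tested on simulated data for the comparison of 1 day with sham. The sham array received noise with an SD of 0.25 on the log2 scale, the robust SD of the differences between the 1 day and 3 days arrays. That pair was the closest of the 10 pairs of arrays, and the robust SD between sham and 1 day was 0.35. Of 11220 genes in that step, 200 were changed. The 2-fold rule called 66 of the 67 genes changed 3-fold, 66 of 66 changed 4-fold, 4 of 67 changed 1.5-fold and 0 of 11020 unchanged genes. With noise this small the last count was largely fixed in advance, so it gives no rate of false calls between real pools. Of 200 unchanged lists, 193 lay inside the tails, and 20 of 20 lists raised by 0.5 on the log2 scale lay above the upper tail. The unchanged lists held the same independent noise as the random lists, and the raise was large against that noise. These list counts were therefore also largely fixed in advance, and they do not imitate members that move together. At the exon level, 200 genes raised by 1 on the log2 scale among 13989 had a median of 1.01.

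The alternatives fixed in advance were centring of the arrays on their medians, quantile normalization, no filter, a filter at the 60th percentile, rules of 1.5-fold and 3-fold, the mean of a gene's clusters, and exon-level medians in place of the gene-level values. Further changes were added after the data were seen, namely all clusters whether named or not, leaving out genes with equal values on any 2 arrays, leaving out 61 muscle genes, and exon-level list medians over genes of both levels. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.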

Results

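Gene expression in the T10 spinal cord was measured with Affymetrix whole-transcript arrays after a sham operation and at 1 day, 3 days, 1 week and 3 weeks after injury. Each of the 5 groups was 1 pool of RNA from 3 mice, so each value below rests on 1 array per group, with no replicate and no test. Signals are log2 values as deposited, and after the filter on low signals 11280 genes were compared. Beside a gene's log2 difference stands, where given, the median ± SD over its exon-level probe sets. That SD is the spread between probes on 1 pair of arrays and says nothing of the spread between mice. The rises and falls called largest below are those among genes with at least 4 probe sets, of which at least 75% moved the same way, and some genes outside this rule had larger differences. A difference is rough in size where the lower of its 2 signals lay below the filter level. The median signal of the gene-level arrays was 4.60 in sham, 4.52 at 1 day, 4.58 at 3 days, 4.59 at 1 week and 4.76 at 3 weeks.

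The design text asks how expression changes over time after injury, with long noncoding RNAs as its subject. At least 2-fold from sham were 427 higher and 461 lower genes at 1 day, 669 and 1080 at 3 days, 1273 and 1572 at 1 week, and 959 and 383 at 3 weeks. Without a replicate, the share of these calls that arises without injury is not known. Of 69 olfactory receptor genes, singled out after the data were seen, 10 were higher and 6 lower at 1 day. They numbered 8 and 4 at 3 days, 13 and 6 at 1 week, and 1 and 5 at 3 weeks. Of the 10 pairs of arrays, sham and 1 week lay farthest apart (2845 genes) and 1 day and 3 days closest (438 genes). The direction of the calls moved with the scaling of the arrays. Higher genes made up 48.1% of the calls at 1 day and 38.3% at 3 days as deposited, against 67.9% and 50.6% after quantile normalization. At 3 weeks they made up 71.5% as deposited and 54.4% after centring on the array medians. The median difference of all tested genes was -0.15 at 1 day, -0.12 at 3 days, -0.06 at 1 week and 0.00 at 3 weeks. Quantile normalization moved it by 0.14, 0.10 and -0.11 at 1 day, 3 days and 3 weeks, and centring by -0.16 at 3 weeks.

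**Figure D1:**
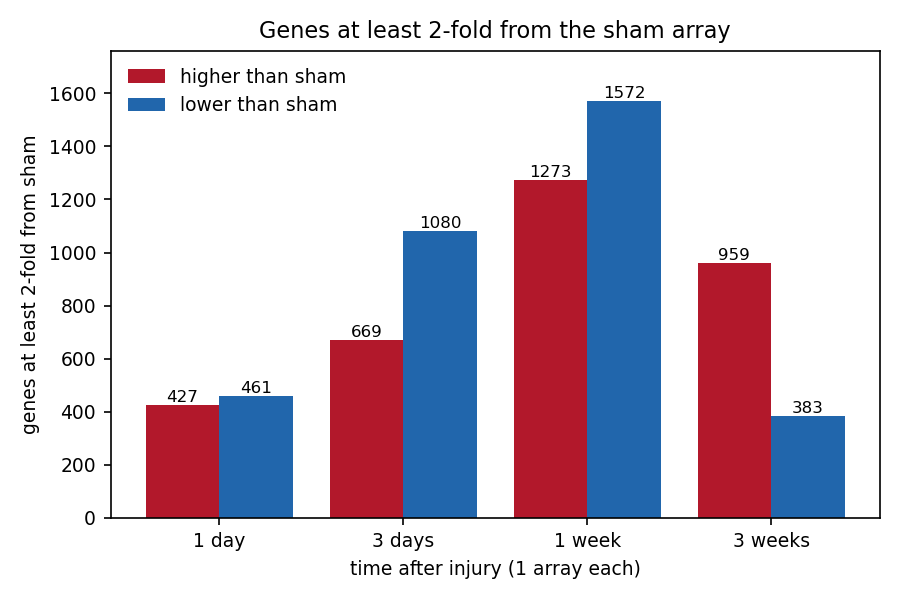
Number of genes at least 2-fold higher (red) or lower (blue) than the sham array at each time after injury, with 1 array per time and 11280 genes compared. The count was largest at 1 week, with 1273 higher and 1572 lower genes.

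At 1 day after injury, the 6 largest rises were in Lcn2, Hmox1, Msr1, Timp1, Ccl3 and Atf3. Lcn2, which encodes the acute-phase protein lipocalin-2 (transcript cluster 6885873), was 63.2-fold higher than in sham, a log2 difference of 5.98 (probe sets 5.85 ± 0.75, n = 8). Hmox1, the haem-degrading oxygenase, rose by 5.75 (5.43 ± 0.62, n = 9), and the chemokine gene Ccl3 by 5.18 (5.64 ± 0.67, n = 4). The macrophage scavenger receptor Msr1 rose by 5.37, the metalloproteinase inhibitor Timp1 by 5.25 and the stress-induced transcription factor Atf3 by 5.05. The sham signals of Msr1, Timp1 and Atf3 lay below the filter level, where array signals say little about the true level, so their folds are rough. The largest falls were in the organic anion transporter Slc22a8 (-2.61, probe sets -2.82 ± 1.37, n = 14), the brain endothelial transporters Slco1c1 (-2.48) and Slco1a4 (-2.11), the oligodendrocyte lineage receptor Gpr17 (-2.32), the GABA receptor subunit Gabrb2 (-2.13) and Ninj2 (-2.11).

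Of the fixed lists at 1 day, 17 lay above and 10 below random lists of matched expression. Lists of unrelated genes would give 1 on each side. Members of a fixed list need not move independently and some lists share members, so these counts are descriptive at every time. Among reactive astrocyte genes 18 of 20 rose, with a median of 2.85 (95% interval over members 2.45 to 3.72, percentile 100). Macrophage and phagocyte genes had 13 of 18 higher and a median of 1.68, with Lgals3 at 4.46. Chemokine genes had 9 of 17 higher (median 1.32, with Cxcl10 at 3.79) and 1 lower, Cx3cl1 at -1.01. Interferon-stimulated genes had 10 of 14 higher (median 1.29), led by Ifit1 at 3.76 and Gbp2 at 2.64. Cytokines and inflammatory mediators had 7 of 11 higher (median 1.26, exon level over 17 members 1.92), with Ptgs2 at 2.77 and Il1rn at 2.49. The sham signals of Cxcl10, Ifit1, Gbp2 and Ptgs2 lay below the filter level. Neutrophil markers had 6 of 14 higher, including Retnlg at 3.26, and a median of 0.61 (exon level 1.40). Immediate early genes had 11 of 18 higher (median 1.27, with Myc at 2.96). Axon regeneration-associated genes had 7 of 13 higher (median 1.30). Their top member Sprr1a was 5.51 at the gene level and 1.95 ± 2.89 over 3 probe sets.

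Skeletal muscle markers had the highest median of the 40 lists at 1 day, with 12 of 12 measured members higher and a median of 3.66 (95% interval 2.89 to 4.45, percentile 100). The myosin light chain Myl1 was at 4.86 (probe sets 6.24 ± 1.49, n = 10, with a sham signal below the filter level) and the skeletal actin Acta1 at 4.69. These genes encode the contractile apparatus of muscle fibres and moved beside the inflammatory lists at this time. The pericyte and smooth muscle list, which holds the muscle genes Tagln and Des (both at 2.38), had a median of -0.28 and lay within random lists.

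Several neuronal lists and the homeostatic microglia list lay below sham at 1 day. The neuron list had a median of -0.52 (95% interval -0.73 to -0.40, percentile 0.02), and 1 of 18 members, the RNA-binding Elavl4 at -1.48, fell by at least 2-fold. Voltage-gated ion channels had 7 of 14 lower (median -0.99), with Kcnd2 at -1.37 and Cacna1e at -1.23. Excitatory transmission genes had 4 of 10 lower (median -0.87), with Grin2a at -1.26, and inhibitory transmission genes 1 of 8 (median -0.76). Homeostatic microglia markers had 9 of 13 lower and a median of -1.18 (percentile 0). Tmem119 was at -2.10, with a 1 day signal below the filter level, and the purinergic receptor P2ry12 at -1.98, while Fcrls was higher at 1.29. Genes of Wnt signalling and axon guidance had 4 of 23 lower (median -0.66), and astrocyte markers 3 of 15 (median -0.47), including the amino acid transporter Slc7a10 at -1.94. The cholesterol synthesis list had a median of -0.53 with 1 of 15 lower (Mvd at -1.38). Endothelial markers went both ways, with Cdh5 at 1.36 and Pecam1 at 1.26 against the transporters named above, and their median of -0.24 lay within random lists. Myelin genes had a median of -0.23, also within random lists, with 4 of 18 lower, led by Aspa at -1.66 and Fa2h at -1.63.

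At 3 days, the largest rises included genes of macrophages. Msr1 was at 6.75 (probe sets 6.72 ± 2.46, n = 11), the phagocyte glycoprotein gene Gpnmb at 6.30 (6.26 ± 1.93, n = 16), the arginase Arg1 at 5.77 and the galectin Lgals3 at 5.69. Hmox1 was at 5.94 (5.69 ± 0.62, n = 9) and Timp1 at 5.65. The largest falls were in Chodl, a gene of motor neurons (-3.26, probe sets -3.44 ± 1.15, n = 9), the hedgehog-binding Hhip (-2.76), the heparan sulfate enzyme Ndst4 (-2.67), the sphingosine phosphate phosphatase Sgpp2 (-2.66) and Ntng1 (-2.62). Mrpl51 was at -2.77 at the gene level and at -0.69 ± 1.05 over 6 probe sets, so its fall rests on the gene-level summary. The sham signals of Msr1, Gpnmb and Timp1, and the 3 day signals of Chodl, Mrpl51 and Ndst4, lay below the filter level.

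At 3 days, 20 lists lay above and 10 below random lists. Macrophage and phagocyte genes had 16 of 18 higher and a median of 3.20 (95% interval 2.01 to 4.44, exon level 3.70). Genes of lysosomes and lipid handling had 12 of 20 higher (median 1.65), with the lipid droplet gene Plin2 at 3.37 and the signalling adaptor Tyrobp at 3.13. Cell cycle genes had 21 of 28 higher and a median of 1.44 (1.15 to 1.69), below the exon-level 2.10, with Ccna2 at 3.73 and Top2a at 3.41. Complement genes had 6 of 10 higher (median 1.92, 0.03 to 3.05, exon level over 14 members 0.84), with C3ar1 at 5.48 and C1qc at 3.26. Reactive astrocyte genes had 18 of 20 higher (median 2.41). Among class II antigen presentation genes, with 4 of 9 listed members measured, 3 of 4 rose (median 2.10), Cd74 at 2.88 and H2-Aa at 2.85. The exon-level median over 7 members was 0.24. Among class I genes 3 of 7 rose (median 0.76, exon level over 10 members 1.43), with Psmb8 at 2.42. Neutrophil markers had 9 of 14 higher (median 1.37, exon level 2.05, S100a9 at 3.79), and chemokines 9 of 17 (median 1.81, Ccl9 at 4.50). Extracellular matrix genes had 11 of 22 higher (median 0.96), with Thbs1 at 4.54, and fibroblast and meningeal genes 8 of 18 (median 0.68), with Mgp at 2.97 and Postn at 2.51. Skeletal muscle markers had 12 of 12 higher with a median of 2.54 (1.99 to 3.11). Schwann cell genes had 4 of 10 higher (median 0.60), led by Gldn at 3.63. Homeostatic microglia markers had a median of 0.56 with 2 of 13 higher, Olfml3 at 1.93 and Gpr34 at 1.18. Top2a, S100a9, Postn and Gpr34 had sham signals below the filter level.

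Neuronal genes were lower at 3 days than sham by more than at 1 day. The neuron list had 9 of 18 lower and a median of -1.10 (95% interval -1.41 to -0.73), with Elavl4 at -2.19 and the neurofilament-associated Ina at -1.78. Excitatory transmission genes had 9 of 10 lower (median -1.59), with the glutamate receptor subunits Grin2b at -2.05 and Gria2 at -1.78. Inhibitory transmission genes had 7 of 8 lower (median -1.45), and voltage-gated ion channels 10 of 14 (median -1.62), with Scn1a at -2.58 and Kcnc1 at -2.12. Motor neuron markers had 3 of 7 lower (median -0.67), the choline transporter Slc5a7 at -2.01 and Chat, which makes acetylcholine, at -1.32. Cholesterol synthesis genes had 12 of 15 lower and a median of -1.28, with Lss at -2.03 and Cyp51 at -1.64. Myelin genes had 5 of 18 lower (median -0.70), with Ugt8a at -1.92. Astrocyte markers had 6 of 15 lower (median -0.91), and Wnt and guidance genes 8 of 23 (median -0.65), with Epha4 at -1.94.

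At 1 week the differences from sham were the most numerous of the 4 times. Gpnmb was 298.3-fold higher, a log2 difference of 8.22 (transcript cluster 6946055, probe sets 8.42 ± 1.57, n = 16). The proton pump subunit Atp6v0d2 was at 7.78 (8.14 ± 1.69, n = 11), the scavenger receptor Cd36 at 7.36 (7.53 ± 1.29, n = 21), the matrix protein gene Postn at 7.10 (7.05 ± 0.87, n = 25), Msr1 at 7.08 and Lgals3 at 6.46. All of these except Lgals3 had sham signals below the filter level. The largest falls were in the sodium channel subunits Scn4b (-4.35, probe sets -4.16 ± 1.47, n = 5) and Scn1a (-4.00, -4.18 ± 0.68, n = 9), the GABA receptor subunits Gabrb2 (-4.29) and Gabra5 (-3.84), the glutamate receptor auxiliary subunit Cacng2 (-3.64) and Lamp5 (-3.60). Gabrb2 was at -2.88 ± 1.08 over 16 probe sets, a smaller fall than at the gene level. The 1 week signals of Scn4b and Gabrb2 lay below the filter level, so the size and rank of their falls are rough.

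At 1 week, 19 lists lay above and 11 below random lists. Macrophage and phagocyte genes had 16 of 18 higher and a median of 4.64 (95% interval 3.49 to 5.91, exon level 5.48). Lysosome and lipid genes had 18 of 20 higher and a median of 3.09 (1.51 to 3.81), with Tyrobp at 4.65 and Plin2 at 4.61. Fibroblast and meningeal genes had 16 of 18 higher and a median of 3.19 (2.40 to 3.90), with the collagen-binding Lum at 5.78 after Postn. Extracellular matrix genes had 20 of 22 higher and a median of 3.11 (2.00 to 3.76), with the macrophage elastase Mmp12 at 5.31 (probe sets 6.32 ± 1.13, n = 12) and Thbs1 at 5.29. Complement genes had 6 of 10 higher (median 3.71, exon level 2.45), and cell cycle genes 22 of 28 (median 2.05, exon level 2.71, with Ccna2 at 4.39). Reactive astrocyte genes had 17 of 20 higher (median 2.26, exon level 2.77), with Timp1 at 5.18 and Emp1 at 4.35. Interferon-stimulated genes had 12 of 14 higher (median 1.47), class II genes 3 of 4 (median 2.62, exon level over 7 members 0.82) and class I genes 5 of 7 (median 1.46, exon level 2.07). Homeostatic microglia markers had 8 of 13 higher and 2 lower (median 1.35). Olfml3 was at 3.10 and Fcrls at 2.68, Slc2a5 at -1.36 and the transcription factor Sall1 at -1.07. Pericyte and smooth muscle genes had 5 of 13 higher (median 0.74), with the smooth muscle actin Acta2 at 3.21. Mmp12 and Timp1 in sham, and Slc2a5 at 1 week, had signals below the filter level. Skeletal muscle markers had 4 of 12 higher and a median of 0.76 (0.45 to 1.25).

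The neuron list at 1 week had 17 of 18 lower and a median of -2.34 (95% interval -2.73 to -1.73), with the synaptic vesicle protein gene Syt1 at -3.18 and Ina at -3.17. Inhibitory transmission genes had 8 of 8 lower (median -2.66), with the glycine receptor subunit Glra1 at -3.20. Excitatory transmission genes had 9 of 10 lower (median -2.25), with the vesicular glutamate transporter Slc17a6 at -3.00. Voltage-gated ion channels had 13 of 14 lower (median -2.32), and motor neuron markers 5 of 7 (median -1.52), with Slc18a3 and Slc5a7 both at -2.75. Myelin genes had 15 of 18 lower and a median of -1.51 (-1.84 to -1.32), with Fa2h at -2.74 and Gpr37 at -2.16. Cholesterol synthesis genes had 15 of 15 lower and a median of -2.14 (-2.67 to -1.67), with Sqle at -2.89 and Cyp51 at -2.83. Astrocyte markers had 3 of 15 lower (median -0.70). Oligodendrocyte precursor markers had 3 higher and 1 lower of 13 and a median of -0.04 within random lists, with Vcan at 2.73 and Bcan at -1.34. Oxidative phosphorylation genes had 0 of 16 past 2-fold and a median of -0.50, also within random lists.

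**Figure D2:**
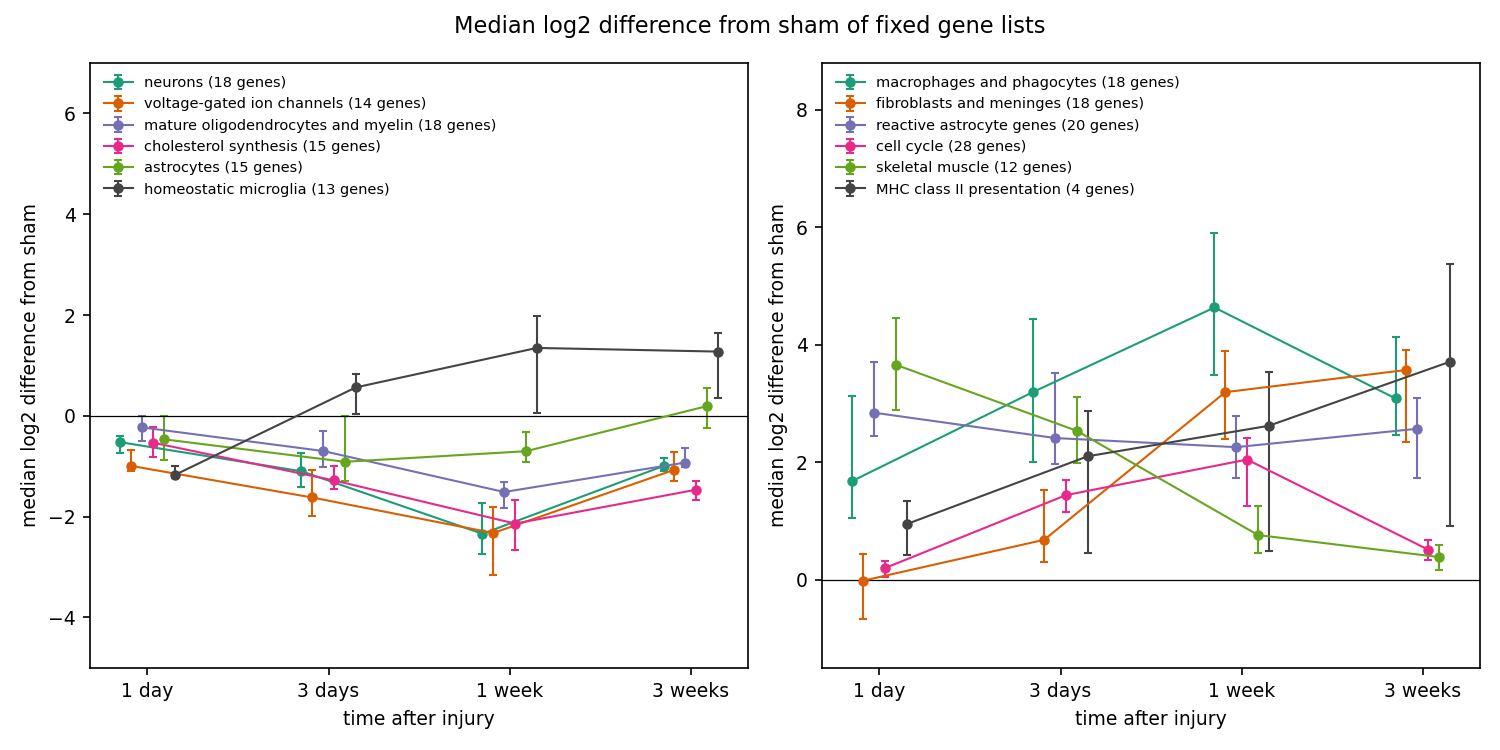
Median log2 difference from sham at each time for 12 of the fixed gene lists, with 95% bootstrap intervals over the members of a list as error bars and 1 array per time. Neurons were lowest at 1 week (-2.34), macrophages and phagocytes highest at 1 week (4.64), and skeletal muscle highest at 1 day (3.66).

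At 3 weeks the rises outnumbered the falls. Gpnmb was at 6.88 (probe sets 6.93 ± 1.86, n = 16), Atp6v0d2 at 6.05, the secreted Wnt-binding gene Sfrp4 at 5.83 (6.35 ± 1.99, n = 7), Postn at 5.56, the lubricant glycoprotein gene Prg4 at 5.51 (5.24 ± 1.19, n = 14) and the lipopolysaccharide-binding Lbp at 5.50. The falls were smaller, and 3 of the 6 largest under this rule were enzymes of sterol synthesis: Sqle at -1.94 (-2.04 ± 0.29, n = 14), Cyp51 at -1.92 (-1.87 ± 0.38, n = 13) and Lss at -1.82 (-2.12 ± 0.41, n = 23). Alas2, the haem synthesis enzyme of red cell precursors, was at -1.97 and Egfl6 at -1.90. Anapc13 was at -2.02 at the gene level and at -0.32 ± 0.99 over 4 probe sets, so its fall rests on the gene-level summary. The sham signals of Gpnmb, Atp6v0d2 and Postn lay below the filter level.

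At 3 weeks, 22 lists lay above and 10 below random lists. Fibroblast and meningeal genes had 18 of 18 higher and a median of 3.57 (95% interval 2.34 to 3.91), with Mgp at 5.18. Extracellular matrix genes had 20 of 22 higher (median 2.46), with Col12a1 at 4.49. Class II antigen presentation genes, with 4 of 9 listed members measured, had 3 of 4 higher and a median of 3.71 (0.91 to 5.38), with Cd74 at 5.38. Complement genes had 8 of 10 higher (median 3.20), with the C1 inhibitor gene Serping1 at 4.89, and macrophage genes 15 of 18 (median 3.09). Lysosome and lipid genes had 14 of 20 higher (median 1.80), with the lipid exporter Abca1 at 3.70. Reactive astrocyte genes had 17 of 20 higher (median 2.57), with Lcn2 at 5.48 and Steap4 at 4.51. Neutrophil markers had 11 of 14 higher (median 1.61), with S100a9 at 4.09. Schwann cell genes had 7 of 10 higher (median 1.13), with Mpzl2 at 3.23, and T and NK cell markers 3 of 10 (median 0.49), with Ccl5 at 2.09 and Cd3g at 2.01 and an exon-level median of 0.13 over 15 members. Homeostatic microglia markers had 7 of 13 higher (median 1.27), with Tgfbr1 at 1.99. Steap4, S100a9, Ccl5 and Cd3g had sham signals below the filter level. Cell cycle genes had 3 of 28 higher (median 0.51), and skeletal muscle markers 1 of 12 (median 0.39, Tnnc2 at 1.21).

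Neuronal and myelin lists stayed below sham at 3 weeks. Neurons had 9 of 18 lower and a median of -0.996 (95% interval -1.09 to -0.84), inhibitory transmission 4 of 8 (median -1.06), excitatory transmission 5 of 10 (median -1.01) and voltage-gated ion channels 8 of 14 (median -1.07), with Scn4b at -1.64 and Scn8a at -1.43. Myelin genes had 6 of 18 lower (median -0.93), with Fa2h at -1.70. Cholesterol synthesis genes had 13 of 15 lower and a median of -1.47 (-1.67 to -1.29). Oxidative phosphorylation genes had a median of -0.38 with 0 of 16 past 2-fold. Wnt and guidance genes had 2 of 23 higher, Sema3c at 1.49 and Wnt5a at 1.09, and a median of 0.26. Astrocyte markers had a median of 0.19 within random lists.

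B and plasma cell markers, with 3 measured members, had 1 higher at 1 week and at 3 weeks, Cd22 at 2.58 and 2.26, and medians of 0.00 and 0.06. Ependymal and cilia genes had 2 of 5 higher at 3 weeks (median 0.91), Pltp at 1.42 and Cfap126 at 1.36. Chondroitin sulfate proteoglycan genes had 1 of 11 higher and 1 lower at 1 week (median 0.09, within random lists). Hypoxia and glycolysis genes had 3 of 14 higher and 1 lower at 1 day, with Adm at 3.82 (probe sets 1.78 ± 1.48) and Ndrg1 at -1.02, and a median of -0.26 within random lists. Cytosolic ribosomal protein genes, with 7 of 27 listed members measured, had 1 higher at 1 day, Rpl37 at 1.02, and a median of 0.51. Heat shock and unfolded protein genes had 3 of 13 higher at 1 day (median 0.29), with Hspa1a at 1.41 (probe sets 3.17 ± 2.49, n = 2) and Ddit3 at 1.07. Of the erythrocyte markers 2 were measured, and Alas2 was lower at every time, at -2.51 at 1 week. Cd22, Adm, Rpl37 and Hspa1a had sham signals below the filter level. The erythrocyte median was -0.85 at 1 day, -0.85 at 3 days, -1.60 at 1 week (percentile 1.05) and -0.94 at 3 weeks, beyond random lists at each time except 3 days, but at 3 weeks the exon-level median over 5 members was -0.09.

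The steps between successive arrays do not use the sham array. From 1 day to 3 days 328 genes were higher and 110 lower. Gpnmb rose by 3.83 (probe sets 3.88 ± 0.77, n = 16), Ccna2, a cyclin of DNA synthesis, by 3.78, Pld4 by 3.36 and Chil3, a gene of alternatively activated macrophages, by 3.35. Steap4 (-2.94), Ptx3 (-2.38) and the haptoglobin gene Hp (-2.29) fell, and Scoc was at -2.42 at the gene level and -0.35 ± 0.98 over 5 probe sets. The 3 day signal of Steap4 lay below the filter level. In this step homeostatic microglia markers had 9 of 13 higher (median 1.37), led by P2ry13 at 2.42, and cell cycle genes 14 of 28 (median 1.01).

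From 3 days to 1 week 622 genes were higher and 361 lower. The largest rises were in Aspn, at 5.16 (probe sets 4.99 ± 1.01, n = 10), Sfrp4 at 5.11 (6.48 ± 2.01, n = 7), C1qtnf3 at 5.11 and Mfap4 at 4.61. Gldn fell by 3.07, Lcn2 by 2.63, Acta1 by 2.50 and Scn4b by 2.36. The 3 day signals of Aspn and C1qtnf3 and the 1 week signal of Scn4b lay below the filter level. Fibroblast and meningeal genes had 16 of 18 higher in this step (median 2.20), while neurons had 13 of 18 lower (median -1.11) and skeletal muscle markers 11 of 12 lower (median -1.91).

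From 1 week to 3 weeks 796 genes were higher and 392 lower. The transporters Slc47a1 (3.23), Slc6a20a (2.98, probe sets 2.90 ± 0.57, n = 12) and Slc13a4 (2.97) rose, and Gabrb2 was at 3.01 at the gene level and 1.65 ± 0.91 over 16 probe sets, its 1 week signal being below the filter level. The largest falls were in Arg1, at -4.50 (-3.96 ± 1.87, n = 10), Cd36 at -4.31 (-4.77 ± 0.60, n = 21), the coagulation factor gene F13a1 at -3.87 and Chil3 at -3.87. Inhibitory transmission genes had 8 of 8 higher (median 1.75), neurons 13 of 18 (median 1.30, with Syt1 at 2.21) and ion channels 10 of 14 (median 1.20). Cell cycle genes had 16 of 28 lower (median -1.28) and macrophage genes 9 of 18 (median -1.14). Of the 1602 genes higher than sham at any time, 991 (61.9%) had their highest signal after injury at 1 week. Of the 1867 lower at any time, 1442 (77.2%) had their lowest signal then.

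Long noncoding RNAs were the subject of the design text. Of 63 that passed the filter, 13 differed from sham by at least 2-fold at any time. Higher and lower were 3 and 4 at 1 day, 2 and 4 at 3 days, 2 and 7 at 1 week, and 3 and 3 at 3 weeks. Exon-level medians of 123 gave 6 and 7, 10 and 11, 9 and 23, and 6 and 5. At the gene level the share called was 11.1% at 1 day, 9.5% at 3 days, 14.3% at 1 week and 9.5% at 3 weeks. Of all tested genes it was 7.9%, 15.5%, 25.2% and 11.9%. At the exon level 32 of 123 were called at 1 week, against 1886 higher and 2248 lower of 14378 genes. The gap at 1 week was thus smaller at the exon level. At 3 weeks, with 11 of 123 against 1321 and 525 of 14378, it was not smaller. Clusters without a single gene symbol are not in these counts. Measured at the exon level alone, the imprinted Meg3 was at -1.74 ± 0.40 (n = 7) and Dnm3os at 3.04 ± 1.38 (n = 4) at 1 week, both singled out after their values were seen. H19, an imprinted RNA abundant in fetal tissue (transcript cluster 6972314), had the largest rise, by 3.16 at 1 day, 3.41 at 3 days, 6.19 at 1 week (probe sets 6.08 ± 0.32, n = 6) and 4.13 at 3 weeks. Snhg5, a host gene of small nucleolar RNAs, was at 1.98 at 1 day, 1.83 at 3 days and 1.42 at 1 week, and its 0.78 at 3 weeks did not pass 2-fold. At 3 weeks 9630028B13Rik was at 1.89 (1.72 ± 1.35, n = 3), with a sham signal below the filter level. Zbtb11os1 was at 1.20 at 1 day (0.81 ± 0.50, n = 2). Airn was at -1.05 at 1 day, short of 2-fold after quantile normalization (-0.92), and 1.25 at 3 weeks, and had no probe set of its own at the exon level.

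Falls of long noncoding RNAs were largest at 1 week. Cdr1os was at -2.47 (probe sets -2.20 ± 0.68, n = 8), 4933431E20Rik at -2.38 (-2.45 ± 0.59, n = 3), Snhg11 at -2.29 (-2.19 ± 0.91, n = 6), Sox2ot at -1.30 (-1.79 ± 0.54, n = 7) and C130071C03Rik at -1.08 (-1.68 ± 0.16, n = 3). Rnf227, which has the long noncoding type in the table used although its name is that of a protein family, was at -2.37. Pantr1 was at -1.52 with 1 probe set at -0.55 and a 1 week signal below the filter level. At 3 weeks Cdr1os was at -1.07, Snhg11 at -1.13 and 4933431E20Rik at -1.02. The list of known long noncoding RNAs, with 7 of 44 listed members measured, had a median of -1.08 at 1 week (95% interval -1.52 to 0.58, percentile 0.43) and an exon-level median of -0.51 over 10 members. Its mean was 0.12, because H19 moved the other way.

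**Figure D3:**
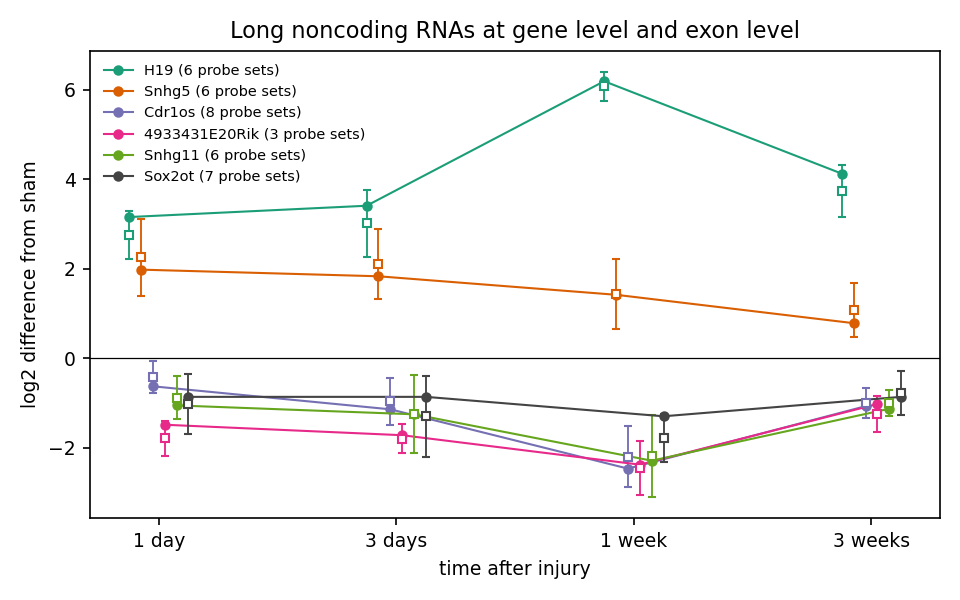
Log2 difference from sham of 6 long noncoding RNAs at each time. Filled circles joined by lines are gene-level values and open squares are exon-level medians, with error bars of 1 SD over the probe sets of 1 pair of arrays. H19 reached 6.19 at 1 week, and Cdr1os was lowest there, at -2.47.

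The exon-level probe sets were set against the gene-level values for 10043 genes with at least 4 probe sets. Across genes, which are not independent replicates, the differences from sham correlated with r between 0.945 (1 day) and 0.975 (1 week). Of the genes called at the gene level, 99.7% or more moved in the same direction at the exon level at each time, and between 82.7% (1 day) and 97.1% (1 week) were also at least 2-fold apart there. Both levels have the same 5 group labels and were taken as coming from the same pools, so this was read as a comparison of summaries and not of animals. Whether they are summaries of the same hybridisations is not given in the sources used here. If they are, much of this agreement was fixed in advance, so it is no independent check of the gene-level values.

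**Figure D4:**
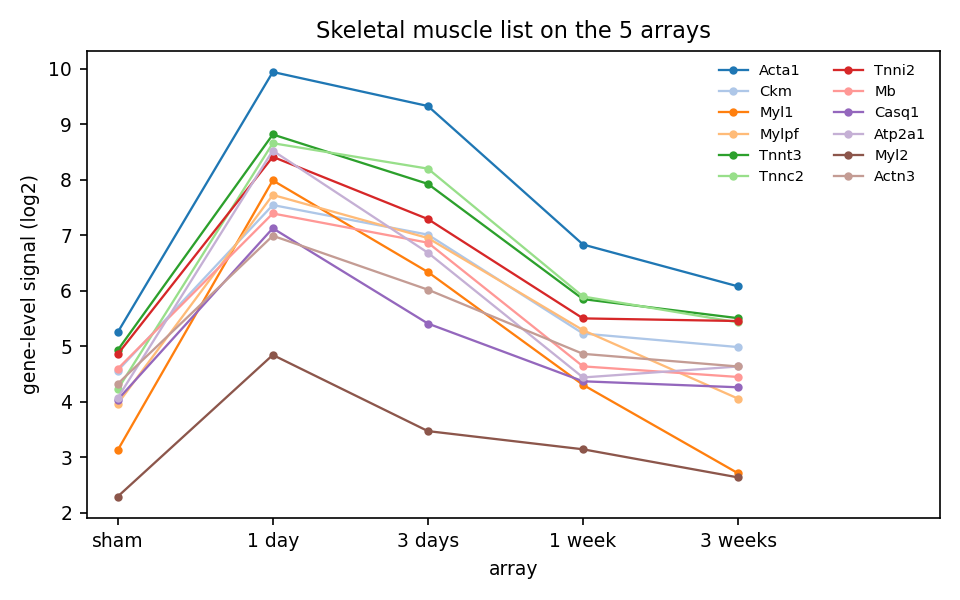
Gene-level log2 signal of the 12 measured skeletal muscle markers on the 5 arrays, with 1 line per gene. Each gene was higher at 1 day than in sham, and Acta1 went from 5.25 in sham to 9.95 at 1 day.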

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

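The tests of dilution of resident cells, with and without myelin genes, of a smaller share of lesion tissue, and of equal values were chosen after the results were seen, as were the intervals on the 2 muscle tests. The other tests were set before.

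Homeostatic microglia markers lay on opposite sides of sham at 2 times, with a median log2 difference of -1.18 at 1 day and 1.35 at 1 week, and this difference between times was not tested. After quantile normalization the value at 1 day was -0.99, short of 2-fold. Transcript clusters with no single gene name, which the comparisons of the report leave out, also differed from sham. Of 3821 past the filter, 477 were at least 2-fold from sham at 1 day, 624 at 3 days, 878 at 1 week and 351 at 3 weeks.

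Skeletal muscle genes were higher in the pools of 1 day and 3 days, with medians of 3.66 and 2.54. If muscle tissue in the RNA were the source, the signal above sham would drop from 1 day to 3 days by 1 common ratio in each gene. The interquartile range of that log2 ratio over the 12 members was 1.17, above the bound of 1 set against this explanation in advance, but its bootstrap interval of 0.34 to 1.40, added once the value was known, spans that bound. A regeneration programme without mature muscle was expected to raise myogenic regulators by at least 1 at 1 day. Their median was 0.027 (95% interval 0.00 to 0.17) over 7 genes between -0.02 and 0.58. However, 5 of them lay below the filter on every array, and Chrnd and Chrng had equal values on all 5 arrays. Myf6, which passed the filter only through its 3 day signal, reached 1.33 at 3 days, from a sham signal below the filter level. Myog, the other gene past the filter, was at 0.03 at 1 day and 0.11 at 3 days. Because most of these genes gave signals near the floor, this test cannot decide on such a programme. Muscle tissue in the RNA cannot be told apart from a change in the cord itself, because each group is 1 pool and muscle carried over at dissection would enter a whole pool.

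Neuronal genes were lowest at 1 week and higher again at 3 weeks. Dilution by incoming cells as the whole cause would lower all resident types alike, provided that their own transcripts did not otherwise change. The neuron median differed from that of astrocyte, endothelial and precursor genes by -2.03 (95% interval -2.50 to -1.21). Myelin genes, which that test left out, fell more like neurons (-1.51), and with them included the difference was -1.61 (-2.06 to -0.92). At 1 week, however, 3 of 16 endothelial genes were at least 2-fold higher and 3 lower. Of 13 precursor genes 3 were higher and 1 lower, and of 15 astrocyte genes 0 were higher and 3 lower. Since some comparison genes rose, these differences cannot decide on dilution. Array scaling does not account for the fall, since the neuron median at 1 week was -2.28 after quantile normalization. A smaller share of lesion tissue at 3 weeks stays open: the fibroblast and meningeal step was 0.14 (-0.45 to 0.38), but after centring its lower end was -0.62, past the bound of -0.5, and loss of neuronal transcripts with recovery, or different animals in each pool, was not tested.

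Many genes had exactly equal values on 2 arrays, 3883 of the tested genes (34.4%), with 154 equal on all 5 arrays. Signal near background is argued against as the whole cause, because 26.9% of 7423 bright genes were tied (95% interval 25.9 to 27.9), but 48.9% of the 3857 other genes were, so it may contribute. Whether the gene-level summary over probes made the ties stays open. Counting each gene once per pair of arrays, 0.53% of 9840 ties had an exon-level median difference of exactly 0, but 1.87% of probe sets were equal on any 2 arrays, so this test had no way to come out otherwise. How the summary was made is not given in the sources used here.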

How the results depend on the processing

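The alternatives with all clusters, without genes of equal values, without muscle genes, and with exon-level list medians over genes of both levels were chosen after seeing the data. The planned change of pseudocount was not run, because the values are already logarithms. Counts are given as higher and lower genes, and the cause of each change below was not tested unless it follows from the rule itself.

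By construction, a 1.5-fold rule gave more genes: 776 and 1873 at 1 day, 1138 and 2455 at 3 days, 1939 and 2616 at 1 week, and 1625 and 1323 at 3 weeks. A 3-fold rule gave 215 and 55, 374 and 246, 745 and 761, and 525 and 18. Exon-level medians gave 674 and 797 at 1 day and 1115 and 1696 at 3 days. For the steps they gave 547 and 284 from 1 day to 3 days, 969 higher from 3 days to 1 week, and 1362 and 643 from 1 week to 3 weeks. Lower genes numbered 669 at 3 weeks after centring on array medians, 240 at 1 day after quantile normalization, and 755 at 1 day with all transcript clusters. The other counts stayed within 1.5 times the reported ones, including all 8 counts against sham under the 60th percentile filter, under the mean of a gene's clusters, without genes of equal values and without muscle genes.

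Long noncoding RNAs higher and lower numbered 5 and 9, 6 and 11, 5 and 14, and 5 and 9 under the 1.5-fold rule, and 6 and 7, 10 and 11, 9 and 23, and 6 and 5 at the exon level. Quantile normalization gave 2 lower at 1 day and 2 at 3 days.

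Of 156 list medians, 151 stayed within their interval after centring, 150 after quantile normalization, 153 without a filter and 146 at the exon level. Many of these intervals over members were wide, so a median could move far and still stay inside. Neutrophil markers at 1 day, for example, went from 0.61 (0.07 to 2.54) to 1.40 at the exon level. The heat shock list at 3 days, 0.18 as reported, was -0.050 at the exon level, also over genes of both levels. The known long noncoding RNAs at 3 weeks, -0.63 as reported, were at 0.038 without a filter. Of the named gene values, 96 stayed within their spread and 3 moved after quantile normalization, against 89 and 8 at the exon level. The 3 were Airn at 1 day and 3 weeks and Pantr1 at 1 week, which have no SD over probe sets. For most other named genes that SD exceeded 0.14, the largest shift of the median difference under quantile normalization. Staying within the spread under that normalization was thus largely fixed in advance. The arrays carry no detection call, so signal over background limits the folds of genes whose lower signal lay below the filter.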

Other observations

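The genes below were chosen after their values were seen, and no explanation was tested. In all, 54 genes were 2-fold higher than sham at one time and 2-fold lower at another. Several of them, Slc13a4 among them, passed 2-fold at 1 day by little. The excess was less than the 0.14 by which quantile normalization moved the median difference of all genes then. The number may thus change with the scaling of the arrays, and it was not computed again after scaling. Slc6a20a was at -1.86 at 1 day and 3.34 at 3 weeks, Slc13a4 at -1.01 and 3.53, Atp13a5 at -1.74 and 1.87, Slc22a8 at -2.61 and 1.15, and Pltp at -2.06 and 1.42. Slc6a13 was at 2.89 and Slc47a1 at 4.22 at 3 weeks. The 1 day signals of Slc6a20a, Slc13a4 and Atp13a5 and the sham signal of Slc47a1 lay below the filter level, so these differences are rough in size.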
